A study of Homo sapiens with 516 samples.

How the data were processed

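Gene expression was measured by 1-colour Affymetrix arrays in 59 established human cancer cell lines of the NCI-60 panel at 0, 100 and 1000 nM doxorubicin and 2, 6 and 24 h. Per the labels' protocols, the lines grew in RPMI-1640 with serum, were plated 24 h before the drug, and the drug reached them in DMSO at a final 0.25%. Total RNA was isolated on columns, kept at an RNA quality score above 7.5 and labelled with biotin in a one-cycle reaction from 1 µg per sample, per the labels' protocols. The authors deposited a single table of log2 values per probe set, with 22277 probe sets and 516 arrays. The log2 scale was read from the values themselves, which run from 2.53 to 14.21. Array medians lay between 4.90 and 5.17 and upper quartiles between 7.25 and 7.80. The method of summarisation and normalization is not given in the sources used here. The changes are therefore relative to an unstated normalization between arrays that makes their distributions nearly alike, and a shift of all transcripts together would not be seen. An alternative with an offset inside the logarithm, planned in case the values were linear intensities, does not apply.

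Groups came from the dose and time in the title of each array, and tissues of origin from the labels. Of the 59 lines, 47 had all 9 arrays, and a line without an array of a comparison was left out of that comparison. No columns of the table were left unmapped, and no arrays were identical in value. As a check of the labels, 515 of 516 arrays correlated best with the other arrays of their own line. The array labelled SK-MEL-2 at 1000 nM and 24 h correlated at 0.743 with UACC-257 and at 0.696 with its own line, both melanoma lines, and results were also computed without SK-MEL-2. For 15 arrays the actin control probe sets differed by more than 1 (log2) between the 3' and the 5' end, against a median of 0.40 over all arrays, and results were also computed without these arrays. Results were computed too without T-47D, whose difference between the arrays labelled 1000 nM and 0 nM ran against the other lines at 6 h and 24 h.

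Probe sets were named through the platform annotation given for the table, which can be old: 19064 probe sets listed 1 gene, 1043 several and 2108 none, apart from 62 controls. A probe set with several genes names none, and some genes of interest, TP53 among them, are unnamed here and not analysed. Of the 11963 genes tested, 11954 had an identifier in a RefSeq table of assembly GRCh38.p14, used for names alone. A gene was represented by the probe set with the highest mean over all arrays, without a filter on low values, and 4310 genes had more than 1. The histone gene listed as HIST1H2BK is named H2BC12. Probe sets whose name ends in _s_at or _x_at can bind transcripts of related genes. A planned relation of the change to gene length was not run, because no gene coordinates of a build tied to this table were used.

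Comparisons were made within cell lines, since the labels give the same line at each dose and time. The difference of log2 values between 2 groups was taken per line and tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), which is the paired test with cell line as the block. P-values were adjusted by Benjamini-Hochberg over all genes of a comparison. A gene was called when the adjusted p was under 0.05 and the mean change at least 1.5-fold (0.585 on the log2 scale). The p-values measure the spread between cell lines. Responses over time were differences of 2 such changes. Responses between tissues were tested with limma's F-test of tissue on the within-line changes, without a fold minimum.

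The comparisons, the tests, the 22 gene lists, the rule for naming genes and all alternatives but those without SK-MEL-2, without T-47D and without the 15 arrays were chosen before the data were examined. The rule named, for each comparison with untreated cells, up to 8 called genes with the largest rises and 8 with the largest falls among those changed that way in at least 80% of lines, and up to 3 called rises and 3 falls per list. It also named the fixed genes CDKN1A, MDM2, GDF15, ATF3, FOS, EGR1, MYC, TOP2A, TOP2B, CCNB1, PLK1, H2BC12 and ABCB1. For differences over time and untreated cells it named up to 5 genes each way, and between tissues the 8 genes with the smallest p. The lists hold p53 targets, immediate early genes, and mitotic, replication, histone, DNA repair, ribosome biogenesis, cholesterol synthesis and oxidative phosphorylation genes. Others hold NF-kB, NRF2, interferon, and TGF-beta and BMP targets, the unfolded protein and integrated stress response, heat shock proteins and apoptosis regulators. The rest are ribosomal proteins, drug transporters, and melanocyte, haematopoietic, epithelial and mesenchymal markers. The apoptosis and p53 lists share 4 genes, BAX, FAS, PMAIP1 and TNFRSF10B. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 22 lists of a comparison, again with the correlation estimated from the data, and with fry. Lists between tissues were tested by permuting tissues over lines (100000 resamples).

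Untreated levels of ABCB1, ABCG2, ABCC1, TOP2A, TOP2B and MDM2 were the mean of a line's arrays at 0 nM. They were set against 2 measures of the response in 3 conditions, 36 relations in all, with Pearson's r and Spearman's rho and two-sided permutation p-values (100000 resamples), adjusted over the family. They were computed again without the 2 lines farthest from the median and with tissue means removed.

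Alternatives were the fit without cell line as a block, a joint fit of all 9 groups, array medians set equal, quantile normalization, and a filter to genes above the median level. Genes were also measured by the mean of all their probe sets or without _s_at and _x_at probe sets. Lines were restricted to those with all 9 arrays, to all but leukemia or (between tissues) prostate lines, or to all but MDA-MB-435, U251 and NCI-ADR-RES, which share an origin with other lines of the panel. Limma with a trend and robust variances and a Wilcoxon signed-rank test were run as well. The tests were tried on simulated data with 200 changed genes. For 1000 nM against 0 nM at 24 h, changes of 2-fold and 3-fold were recovered for 100% of genes and changes of 1.5-fold for 30%, with 0 false calls. A 1.5-fold change lies at the fold minimum itself, which limits its recovery, and 88% of these genes passed the adjusted p alone. Without the fold minimum, 7 unchanged genes were below the adjusted threshold. For the tissue test of the same comparison, a 3-fold shift given to the 3 lines drawn as leukemia was recovered for 47% of genes, with 8 false calls. At 6 h, with 6 such lines, it was 98.5%, with 4 false calls. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and, in R, version 1.17.8 of data.table were used.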

Results

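Doxorubicin is an anthracycline that intercalates into DNA and traps topoisomerase II on it. Transcript levels were measured on Affymetrix arrays in 59 established human cancer cell lines of the NCI-60 panel, left without drug (0 nM) or given 100 nM or 1000 nM doxorubicin for 2, 6 or 24 h. The series sets side by side, over time, the transcriptional responses of this panel to a set of anticancer agents, and doxorubicin is the agent analysed here. The lines came from 9 tissues: 9 lung, 9 melanoma, 8 renal, 7 ovarian, 6 breast, 6 CNS, 6 colon, 6 leukemia and 2 prostate lines. The 516 arrays fell into 9 groups: 58, 59 and 59 arrays without drug, 59, 58 and 57 with 100 nM, and 57, 59 and 50 with 1000 nM at 2, 6 and 24 h. There was 1 array per line, dose and time, so the lines are the replicates of each comparison. The value of a single line has no replicate check, and the number of arrays limits the precision. All changes are means of within-line log2 differences ± SD over lines, with limma's test and Benjamini-Hochberg adjustment over 11963 genes. A gene is said to have risen or fallen when the adjusted p was under 0.05 and the mean change at least 1.5-fold.

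Time in culture without drug gave the background of the time course. Between 2 h and 6 h without drug, FAM200C rose by 0.82 ± 0.48 (SD, n = 58; 54 of 58 lines), and NR1D2, a clock-linked nuclear receptor, fell by 0.69 ± 0.47. From 6 h to 24 h, INSIG1, which restrains sterol synthesis, rose by 0.72 ± 0.60 (54 of 59 lines), and SCD, the stearoyl-CoA desaturase, rose by 0.59 ± 0.39 (58 of 59 lines). The actin-associated TAGLN fell by 0.63 ± 0.61. Over the whole span from 2 h to 24 h, DDIT4, a stress-induced inhibitor of mTORC1, rose by 0.92 ± 0.84 (51 of 58 lines), while MAFF, DLX2, CCN2, SMAD7 and KLF11 fell by 0.84, 0.80, 0.79, 0.72 and 0.70. In all, 1 gene rose and 4 fell from 2 h to 6 h, 2 rose and 1 fell from 6 h to 24 h, and 3 rose and 17 fell from 2 h to 24 h. ATF3 without drug fell by 0.60 ± 1.01 from 2 h to 24 h, the opposite direction to its changes with doxorubicin. Among the gene lists, cholesterol synthesis genes were shifted up from 6 h to 24 h (1 of 14 rose; camera adjusted p = 6.01e-08, and adjusted p = 0.0926 with an estimated correlation). Oxidative phosphorylation genes were shifted up from 2 h to 24 h with none of 32 passing the fold minimum (adjusted p = 1.82e-11, and adjusted p = 0.0581 with an estimated correlation). In untreated cells, TGF-beta and BMP targets were shifted down from 2 h to 6 h, with no member called (adjusted p = 0.00042, and adjusted p = 0.086 with an estimated correlation). Of the 66 list tests of untreated cells, 24 passed and none held with an estimated correlation (lowest adjusted p = 0.0581).

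The lower dose gave small early changes. With 100 nM for 2 h, ATF3, a stress-induced transcription factor, was 0.27 ± 0.21 above the untreated level (n = 58; 54 of 58 lines; adjusted p = 6.13e-11), and PLK1, the mitotic kinase, stood at −0.14 ± 0.16 (12 of 58 lines above 0; adjusted p = 4.78e-06). After 6 h, CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, stood at 0.45 ± 0.73 (42 of 58 lines), MDM2, the ubiquitin ligase of p53, at 0.39 ± 0.77, PLK1 at −0.34 ± 0.37 (4 of 58 lines above 0) and CCNB1, cyclin B1, at −0.23 ± 0.20. None of these reached 1.5-fold, and limma called 0 genes at either time. Without the fold minimum, 494 genes were below the adjusted threshold at 2 h (2019 at an unadjusted p under 0.05) and 1474 at 6 h (2907 unadjusted).

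Several list calls at 100 nM, at times when limma called 0 genes, held with an estimated correlation between genes. The 36 mitotic genes averaged −0.087 ± 0.068 at 2 h (6 of 58 lines above 0; camera adjusted p = 8.45e-39, and adjusted p = 5.01e-06 with an estimated correlation). They averaged −0.184 ± 0.18 at 6 h (3 of 58 lines above 0; adjusted p = 7.59e-46, and adjusted p = 0.00603 with an estimated correlation). The 29 p53 targets averaged 0.201 ± 0.294 at 6 h (52 of 58 lines above 0; adjusted p = 1.66e-20, and adjusted p = 0.0258 with an estimated correlation). Replication genes were shifted up at 2 h (adjusted p = 0.00048 with an estimated correlation) and at 6 h (adjusted p = 0.0258 with an estimated correlation), immediate early genes at 2 h (adjusted p = 0.0114 likewise) and oxidative phosphorylation genes at 6 h (adjusted p = 0.00603 likewise). Other calls were lost with an estimated correlation: p53 targets at 2 h upward (adjusted p = 0.000121, and adjusted p = 0.0524 with an estimated correlation), and 4 lists at 6 h. Of these, cholesterol synthesis genes (adjusted p = 0.0274 and 0.0691) and ribosomal proteins (0.0186 and 0.229) were shifted up. Ribosome biogenesis genes (adjusted p = 0.000955 and 0.0717) and histone genes (0.0487 and 0.229) were shifted down, the second p of each with an estimated correlation, and the histone call ended without T-47D (adjusted p = 0.0915). The immediate early call at 2 h ended with the mean of all probe sets per gene and in the lines with all 9 arrays.

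With 100 nM at 24 h, 25 genes rose and 30 fell. ATF3 rose by 1.25 ± 1.07 (n = 57; 55 of 57 lines), CDKN1A by 1.23 ± 0.90 (53 of 57), TP53I3, a p53-induced oxidoreductase, by 1.00 ± 1.02 (54 of 57). GDF15, a stress cytokine, rose by 0.93 ± 1.30 (47 of 57). KLF4, SAT1, MR1 and CASD1 rose by 0.78, 0.74, 0.74 and 0.73, CASD1 in 56 of 57 lines. PLK1 fell by 1.22 ± 0.92 (3 of 57 lines above 0), and the kinesin KIF20A by 1.17 ± 1.08. The kinetochore motor CENPE fell by 0.94 ± 0.86 and CDC20, an activator of the anaphase-promoting complex, by 0.93 ± 0.95. PSRC1, CDCA3, ASPM and DEPDC1 fell by 0.88, 0.85, 0.85 and 0.84. In all, 4042 genes were below the adjusted threshold without the fold minimum.

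Of the 29 p53 targets, 7 rose and none fell at 100 nM and 24 h. Besides CDKN1A, TP53I3 and GDF15, they included the death receptor FAS (0.64 ± 0.77) and MDM2 (0.61 ± 1.10). The list mean was 0.431 ± 0.463 and lay above 0 in 57 of 57 lines (camera adjusted p = 1.33e-13, and adjusted p = 0.105 with an estimated correlation). Of the 36 mitotic genes, 15 fell and none rose (mean −0.55 ± 0.767; adjusted p = 3.85e-18, and adjusted p = 0.17 with an estimated correlation). Among 22 NF-kB targets, CXCL8, the neutrophil chemokine, rose by 0.76 ± 1.15 and TNFAIP3, a feedback inhibitor of the pathway, by 0.62 ± 0.69 (adjusted p = 2.68e-06, and adjusted p = 0.105 with an estimated correlation). Interferon-stimulated genes were shifted up, with 0 of 29 called (adjusted p = 1.21e-08, and adjusted p = 0.105 with an estimated correlation). So were oxidative phosphorylation genes (0 of 32; adjusted p = 0.000546, and adjusted p = 0.167 with an estimated correlation). Ribosome biogenesis genes were shifted down (0 of 21; adjusted p = 2.33e-10, and adjusted p = 0.105 with an estimated correlation). So were heat shock proteins (0 of 13; adjusted p = 0.00162 and 0.105) and cholesterol synthesis genes (0 of 14; adjusted p = 0.00125 and 0.214). Histone genes were shifted down as well (0 of 28; adjusted p = 0.0248, and adjusted p = 0.562 with an estimated correlation), a call that ended without T-47D (adjusted p = 0.101). Immediate early genes (2 of 30 rose; adjusted p = 0.0147, and adjusted p = 0.391 with an estimated correlation) and apoptosis regulators (1 of 23 rose; adjusted p = 0.00125 and 0.105) were shifted up. In these and all dose and time comparisons, the counts adjusted over the list alone equalled those over all genes, apart from 1 more NRF2 target that rose with 1000 nM at 24 h (3 against 2). The MDM2 call ended without T-47D (0.58), and the GDF15 call rested on 1 of its 2 probe sets, the other having a mean level of 3.35 and a change of 0.04.

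**Figure D1:**
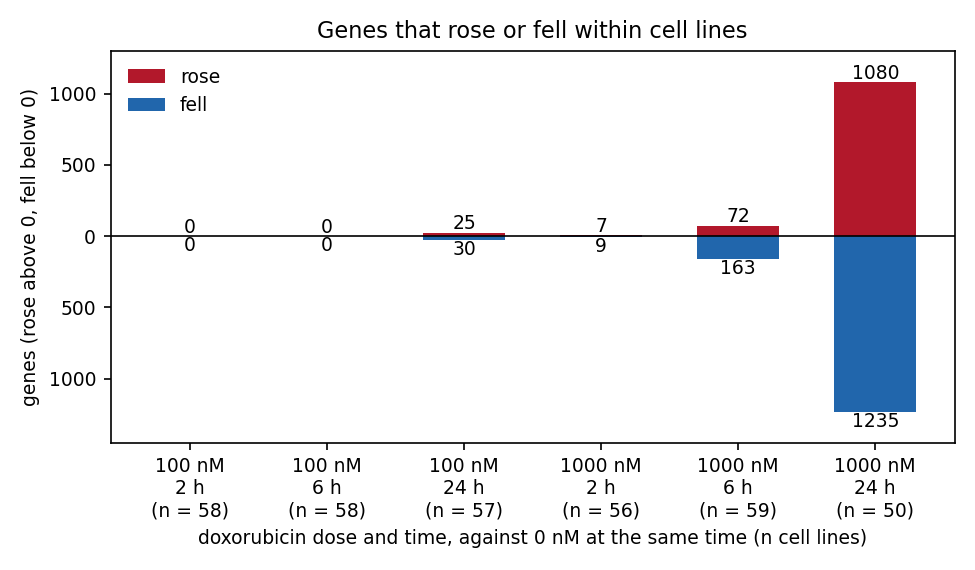
Genes that rose (above 0) and fell (below 0), as counts, for each dose and time. The bars for 1000 nM against 0 nM grew from 7 and 9 genes at 2 h to 72 and 163 at 6 h and 1080 and 1235 at 24 h.

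With 1000 nM, 16 genes changed within 2 h. ATF3 rose by 0.88 ± 0.52 (n = 56; 55 of 56 lines), RSRP1, an arginine- and serine-rich nuclear protein, by 0.85 ± 0.40 (56 of 56). VAMP1, a vesicle fusion protein, rose by 0.80 ± 0.42 and TNFSF9, the ligand of 4-1BB, by 0.77 ± 0.50. FAM53C, RGS2 and the transcription factor IRF1 rose by 0.63, 0.62 and 0.61. NRF1, a transcription factor of nuclear genes for mitochondrial proteins, fell by 0.82 ± 0.40 (1 of 56 lines above 0), and the growth regulator MYC by 0.68 ± 0.47. The clock-linked repressor BHLHE40 fell by 0.67 ± 0.54 and BORA, an activator of Aurora A, by 0.64 ± 0.40 (0 of 56 above 0). PPP1R10, KLF6, JMJD1C and JARID2 fell by 0.62, 0.61, 0.60 and 0.60. The KLF6 change came from a probe set ending in _s_at, without which it was −0.03. CDKN1A stood at 0.50 ± 0.42 (51 of 56 lines), under the fold minimum.

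In all, 7 genes rose and 9 fell at 2 h, and 3513 were below the adjusted threshold without the fold minimum. After quantile normalization the split was 8 and 6. No mitotic gene was called, yet the 36 mitotic genes averaged −0.171 ± 0.098 and lay below 0 in each of the 56 lines (camera adjusted p = 3.21e-27, and adjusted p = 0.00249 with an estimated correlation). The p53 targets and the replication genes were shifted up (adjusted p = 0.00106 for each, and adjusted p = 0.346 for each with an estimated correlation). Immediate early genes, of which 1 rose and 2 fell, did not pass as a list (adjusted p = 0.112). Without cell line in the model, 7 genes were called.

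By 6 h, 1000 nM had changed 235 genes. ATF3 rose by 1.78 ± 1.06 (n = 59; 56 of 59 lines), GCH1, the first enzyme of tetrahydrobiopterin synthesis, by 1.36 ± 0.79. TNFSF9 rose by 1.26 ± 1.05 and CSRNP2 by 1.19 ± 0.77. FAM53C, IRF1, CDKN1A and the general transcription factor GTF2B rose by 1.05, 0.97, 0.97 and 0.96. NRF1 fell by 1.63 ± 0.73, the spindle protein PSRC1 by 1.45 ± 0.95, and BORA by 1.33 ± 0.77. PLK1 fell by 1.32 ± 0.82 and H2AX, the histone variant phosphorylated at DNA breaks, by 1.21 ± 0.65. Each of these 5 fell in 56 of 59 lines. ZMIZ1, cyclin F (CCNF) and PHLDA1 fell by 1.20, 1.18 and 1.15.

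Of the 36 mitotic genes, 17 fell and none rose at 1000 nM and 6 h, with CENPE (−1.06 ± 0.70) and CCNB1 (−0.68 ± 0.43) among them. The list mean was −0.561 ± 0.34 and lay above 0 in 3 of 59 lines (camera adjusted p = 5.57e-24, and adjusted p = 0.12 with an estimated correlation). Of the 29 p53 targets, 7 rose, including TP53I3 (0.72 ± 0.67; 59 of 59 lines), the pro-apoptotic PMAIP1 (0.73 ± 0.91) and the death receptor TNFRSF10B (0.71 ± 0.73). The list mean was 0.32 ± 0.413 (adjusted p = 6.96e-05, and adjusted p = 0.547 with an estimated correlation). Of the 22 NF-kB targets, NFKBIA, TNFAIP3 and CD83 rose by 0.64, 0.59 and 0.59 (adjusted p = 0.0207, and adjusted p = 0.564 with an estimated correlation). Immediate early genes split, FOS and DUSP5 among the 4 that rose (0.70 ± 0.88 and 0.69 ± 0.84) and MYC and FOSL1 among the 4 that fell (−0.99 ± 0.76 and −0.65 ± 0.91). The list did not pass (adjusted p = 0.508). TGF-beta and BMP targets split likewise, ID2 and BAMBI rising by 0.88 and 0.61 and ID3 and ID1 falling by 0.79 and 0.66 (adjusted p = 0.225). Oxidative phosphorylation genes were shifted up with 0 of 32 called (mean 0.11, above 0 in 56 of 59 lines; adjusted p = 8.28e-10, and adjusted p = 0.107 with an estimated correlation). Ribosomal proteins were shifted up (adjusted p = 0.0475, and adjusted p = 0.547 with an estimated correlation), a call that ended, among other settings, without T-47D (adjusted p = 0.0609). Downward shifts passed for DNA repair genes (adjusted p = 0.0475 and 0.547) and ribosome biogenesis genes (adjusted p = 0.0178 and 0.536), the second p of each with an estimated correlation. Interferon-stimulated genes (3 of 29 rose, IFIH1 and IRF7 by 0.61 each; adjusted p = 0.102) did not pass as a list. Single members changed in other lists that did not pass: the replication licensing factor CDC6 rose by 0.62 ± 0.47 and the chaperone DNAJB1 fell by 0.89 ± 0.74. Of the unfolded protein and integrated stress response, DNAJB9 rose by 0.74 ± 0.52 and HERPUD1 fell by 0.75 ± 0.57. EGR1, at 0.57 ± 1.13, was not called, but was without T-47D (0.65), without leukemia lines (0.59) and after median or quantile scaling (0.60 each). In all, 72 genes rose and 163 fell, 19 of the 235 by at least 2-fold. In T-47D the difference between the arrays labelled 1000 nM and 0 nM ran against the other lines (mitotic list mean 1.039, p53 list mean −0.332).

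At 24 h the changes with 1000 nM were the broadest of the doses and times tested. ATF3 rose 17.5-fold (4.13 ± 1.67, n = 50; 49 of 50 lines), ULBP2, a ligand of the NKG2D receptor on lymphocytes, by 3.33 ± 1.79. GCH1 rose by 3.02 ± 1.33 and CHCHD7 by 2.65 ± 1.21, and ULBP2, GCH1 and CHCHD7 each rose in 49 of 50 lines. The histone gene H2AC17, TEX14, the lysosomal protease CTSV and the histone gene H2BC21 rose by 2.59, 2.59, 2.54 and 2.53. H2AC17 and TEX14 started from untreated levels of 3.94 and 3.92, where background signal limits the change that can be seen, so their values here and below have no firm rank. The same limit holds below for FOSB (3.84) and H2AC8 (4.10). SLC19A1, the reduced folate carrier, fell by 2.51 ± 1.20, PFAS, an enzyme of purine synthesis, by 2.11 ± 1.03 and FPGT by 2.02 ± 1.05. The nuclear lamin LMNB1 fell by 2.01 ± 1.14 and NBN, a member of the MRE11 complex at DNA breaks, by 1.99 ± 1.10. HNRNPDL, PLK1 and CUTC fell by 1.95, 1.91 and 1.90.

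Of the 29 p53 targets, 15 rose and none fell at 1000 nM and 24 h. TP53I3 rose by 2.12 ± 1.62, CDKN1A by 2.07 ± 1.19, the DNA damage sensor DDB2 by 1.56 ± 0.78, each in 49 of 50 lines, and MDM2 by 0.78 ± 1.51 (33 of 50). The list mean was 0.743 ± 0.695, above 0 in 49 of 50 lines (camera adjusted p = 0.000389, and adjusted p = 0.561 with an estimated correlation). That second p was 0.561 for each of the lists given here as shifted, and it follows the first below. Of the 28 histone genes measured, 14 rose, among them H2AC8 (2.09 ± 1.75) and H2BC12 (1.41 ± 1.03; 44 of 50 lines), with a list mean of 0.848 ± 0.566 (adjusted p = 1.66e-05 and 0.561). In the same lines the poly-A spike-in controls stood at 0.326 ± 0.814 and the 3' minus 5' difference of the actin control probe sets at 0.212 ± 0.177. Of the 30 immediate early genes, 16 rose, DUSP5 by 1.88 ± 1.46, FOS by 1.87 ± 1.38, EGR1 by 1.85 ± 1.58 and FOSB, from its low level, by 2.26 ± 1.86. MYC alone fell (−0.71 ± 0.98; list adjusted p = 0.000972 and 0.561). Of the 29 interferon-stimulated genes, 12 rose, led by OASL (2.14 ± 1.67), IFI6 (1.97 ± 1.08) and IRF7 (1.95 ± 1.35; list adjusted p = 0.000516 and 0.561). Of the 36 mitotic genes, 21 fell, the checkpoint kinase BUB1B by 1.84 ± 1.32, and BUB1B and cyclin A2 (CCNA2) each in 49 of 50 lines (list adjusted p = 1.66e-05 and 0.561). CDC25C, the phosphatase that activates CDK1, was called as a rise (0.83 ± 1.16), though at 0.16 without its _s_at and _x_at probe sets. DNA repair genes (7 of 27 fell, the kinase CHEK2 by 1.11 ± 0.86; adjusted p = 0.0105 and 0.561) and ribosome biogenesis genes (6 of 21 fell, RRS1 by 0.89 ± 0.63; adjusted p = 0.00865 and 0.561) were shifted down. So were cholesterol synthesis genes (3 of 14 fell, the epoxidase SQLE by 1.29 ± 0.86, list adjusted p = 0.0454 and 0.561), a call that ended without SK-MEL-2 (adjusted p = 0.062). LSS was among the 3, and a dim probe set of the same gene rose by 0.33.

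**Figure D2:**
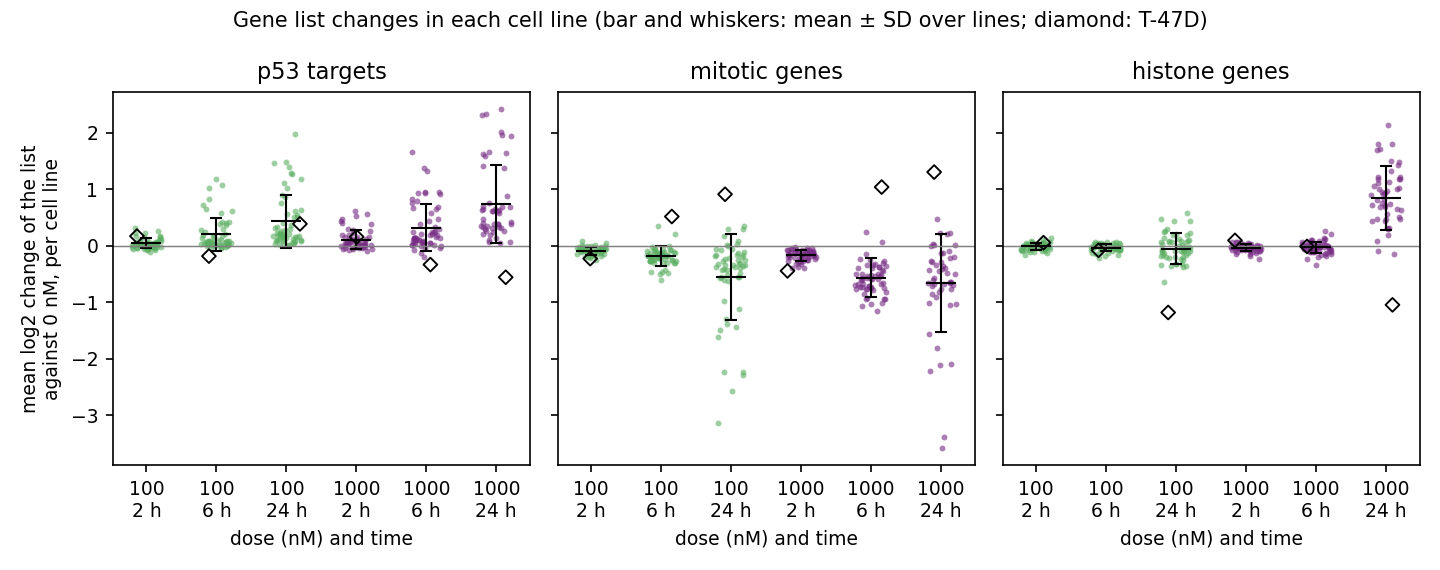
Mean log2 change against 0 nM of the p53 target, mitotic and histone lists in each cell line, by dose and time, with the mean ± SD over lines as bar and whiskers and T-47D as a diamond. The histone list mean, −0.048 ± 0.28 with 100 nM at 24 h, reached 0.848 ± 0.566 with 1000 nM at 24 h, where T-47D lay at −1.044.

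Other lists held members that changed at 1000 nM and 24 h without passing as lists. The unfolded protein and integrated stress response split, with 8 of 26 rising (DDIT3 by 2.30 ± 1.45, PPP1R15A by 1.97 ± 1.11, DNAJB9 by 1.62 ± 0.90) and 4 falling (SLC7A11 by 1.05 ± 1.11, ATF4 by 0.68 ± 0.93; adjusted p = 0.59). The mean of this list, 0.272, and its median, −0.029, differed in sign. NF-kB targets had 6 of 22 rising (NFKB2 by 1.12 ± 0.90, the adhesion molecule ICAM1 by 1.06 ± 0.87; adjusted p = 0.0794). Replication genes had 2 rising (TK1, thymidine kinase, by 1.16 ± 0.84) and 10 of 34 falling (POLE2 by 1.12 ± 1.32; adjusted p = 0.153). TGF-beta and BMP targets had 4 of 15 rising (ID2 by 2.04 ± 1.69, BAMBI by 1.75 ± 1.57) and ID3 falling by 0.83 ± 1.47 (adjusted p = 0.179). Heat shock proteins had 1 rising (BAG3 by 0.65 ± 0.62) and 3 of 13 falling (DNAJB1 by 1.03 ± 0.60, the mitochondrial chaperone HSPD1 by 0.82 ± 0.43; adjusted p = 0.0955). Apoptosis regulators had 6 rising, PMAIP1 by 1.46 ± 1.41 and TNFRSF10B by 1.39 ± 0.86. BCL2L2, an anti-apoptotic protein, was the 1 of 23 that fell (−0.76 ± 0.78; adjusted p = 0.59). Among 9 drug transporters, ABCC5 rose by 0.87 ± 0.80 and ABCC4 and ABCC1 fell by 0.93 and 0.76 (adjusted p = 0.9; mean −0.036, median 0.041). ABCB1, the P-glycoprotein efflux pump, was not called (0.21 ± 0.51). NRF2 targets (2 rose and 1 of 15 fell; adjusted p = 0.459), oxidative phosphorylation genes (1 rose and 2 of 32 fell; adjusted p = 0.179) and epithelial markers (1 of 10 fell; adjusted p = 0.81) did not pass. Ribosomal proteins, melanocyte, mesenchymal and haematopoietic markers held 0 called members (adjusted p = 0.341, 0.858, 0.962 and 0.855). Of the drug's targets, TOP2B, topoisomerase II beta, fell by 0.72 ± 0.45 (49 of 50 lines), and TOP2A, topoisomerase II alpha, stood at −0.47 ± 0.77, not called.

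In all, 1080 genes rose and 1235 fell with 1000 nM at 24 h, 686 of them by at least 2-fold. In T-47D the difference between the arrays labelled 1000 nM and 0 nM ran against the other lines here too (ATF3 −3.27, CDKN1A −1.61). Relative to its untreated 2 h array, ATF3 stood at 3.85 in the array labelled 0 nM and at 0.59 in that labelled 1000 nM. Without this line 1161 genes rose and 1319 fell. The calls of GDF15 (1.24 ± 1.55) and MDM2 ended without _s_at and _x_at probe sets (0.05 for each).

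The 2 doses were also compared directly. At 2 h, RSRP1, TNFSF9, ATF3 and VAMP1 were 0.64, 0.62, 0.60 and 0.59 higher with 1000 nM than with 100 nM (n = 57), and BHLHE40 and NRF1 fell by 0.62 and 0.60. At 6 h, ATF3 was 1.53 ± 0.81 higher, GCH1 1.17 ± 0.57 and CSRNP2 1.04 ± 0.58 (n = 58). NRF1 fell by 1.25 ± 0.47, PHLDA1 by 1.10 ± 0.89, H2AX by 1.09 ± 0.46, PSRC1 by 1.05 ± 0.59 and PLK1 by 0.98 ± 0.57. The mitotic list was lower with the higher dose at 2 h (0 of 36 called; adjusted p = 2.86e-15, and adjusted p = 0.0109 with an estimated correlation) and at 6 h (7 of 36 fell; adjusted p = 5.81e-23, and adjusted p = 0.113 with an estimated correlation). With no member called, p53 targets (adjusted p = 0.01 and 0.416) and NRF2 targets (0.0258 and 0.265) were higher at 2 h, the second p of each with an estimated correlation. At 6 h, NF-kB targets (adjusted p = 0.00136 and 0.583), oxidative phosphorylation genes (9.25e-08 and 0.113) and p53 targets (0.0382 and 0.75) were higher and DNA repair genes (0.015 and 0.404) lower, in the same order of p and with no member called. In all, 4 genes rose and 2 fell at 2 h, and 37 rose and 74 fell at 6 h. After quantile normalization the split at 2 h was 4 and 1. The VAMP1 call ended without T-47D (0.58), while MYC, at −0.58 ± 0.43, was called without it (−0.59).

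With 1000 nM rather than 100 nM for 24 h, 825 genes rose and 1047 fell. ATF3 was 2.89 higher in 49 of 50 lines, ULBP2 2.84 ± 1.22, H2AC17 2.75 ± 1.58, TEX14 2.64 ± 1.81 and CHCHD7 2.50 ± 0.87 (n = 50). SLC19A1 fell by 2.01 ± 0.99, PFAS by 1.96 ± 0.78, ZNF512B by 1.81 ± 1.12, FPGT by 1.72 ± 0.83 and NBN by 1.69 ± 0.87. Of the 28 histone genes, 15 rose, H2BC12 by 1.62 ± 1.00 in 49 of 50 lines (adjusted p = 1.28e-08, and adjusted p = 0.675 with an estimated correlation). Immediate early genes (14 rose and JUND fell; adjusted p = 0.00465 and 0.709) and interferon-stimulated genes (10 rose and 1 fell; adjusted p = 0.0218 and 0.967) were higher, and DNA repair genes lower (7 of 27 fell; adjusted p = 0.00465 and 0.709), the second p of each with an estimated correlation. The interferon list's fall was IFI44 (−0.65), which was not called without _s_at and _x_at probe sets (0.127, p = 0.221). The p53 targets (11 rose and TRIAP1 fell; adjusted p = 0.13) and the mitotic genes (2 rose and 6 fell; adjusted p = 0.3) did not pass as lists. CDKN1A was 0.90 ± 1.31 higher, MDM2 0.14 ± 1.25 and not called. TOP2B, at −0.57 ± 0.38, was called without T-47D (−0.59).

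Of the 25 genes that rose with 100 nM at 24 h, 23 rose with 1000 nM, against 2.26 for independent lists, and of the 30 that fell, 24 fell, against 3.1; 0 moved the other way. Independent lists leave out that the 2 doses share the untreated arrays. In 100 draws of unchanged groups with these shared arrays, at most 1 gene was called in either direction for either dose, so the draws, whose overlap was 0, cannot measure what the shared arrays add. With disjoint random sets of lines for the 2 doses, medians of 18.5 and 22 genes rose and fell for both, 80% and 77.1% of those called with 100 nM, against 2.18 and 2.96 for independent lists. The correlation of the 2 doses' mean changes across genes, which are not independent replicates, was taken in the same ways. At 24 h it was 0.563 over 50 lines, and 0.513 at the median of 100 draws of disjoint lines. With the signs of the lines drawn at random on changes centred per gene, its median was 0.433. There 2.5% of draws lay above 0.572, a limit over the observed value. These draws remove the mean effects, but keep the shared arrays and each line's own departure from the mean response. They thus do not show what the shared arrays alone would give. The covariance was 0.0361, against a median of 0.00156 with random signs and 2.5% of draws above 0.00297. At 6 h the correlation was 0.714 (0.565 from disjoint draws; median 0.482 and upper 2.5% limit 0.577 with random signs; covariance 0.00706 against 0.00048). At 2 h it was 0.711 (0.491 from disjoint draws; 0.458 and 0.539 with random signs; covariance 0.00263 against 0.00035).

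Responses over time were tested as differences of changes. For 1000 nM between 2 h and 6 h, GCH1 gained 0.99 ± 0.78 (n = 56; 53 of 56 lines) and ATF3 0.92, while PLK1 fell by a further 1.04 ± 0.83 (53 of 56 lines), PSRC1 by 0.99 and H2AX by 0.95. Between 6 h and 24 h, H2AC17 gained 2.63 ± 1.81 (47 of 50 lines), H2BC21 2.55 ± 1.54, ULBP2 2.48 ± 1.35 and ATF3 2.44 ± 1.22 (49 of 50). PFAS fell by a further 1.86 ± 0.94 (48 of 50), SLC19A1 by 1.81 and SRI by 1.78. For 100 nM between 6 h and 24 h, ATF3 gained 1.02 ± 1.11 (52 of 56 lines) and CDKN1A 0.81 ± 0.67, and PLK1 fell by a further 0.88 ± 0.80 (50 of 56 lines). In all, 12 genes gained and 34 lost for 1000 nM from 2 h to 6 h (15 and 26 after either median or quantile scaling). Another 791 gained and 803 lost from 6 h to 24 h, and 10 gained and 9 lost for 100 nM from 6 h to 24 h. From 2 h to 6 h at 100 nM, limma called 0 genes (163 below the adjusted threshold without the fold minimum, 1751 at an unadjusted p under 0.05).

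As lists, mitotic genes fell further from 2 h to 6 h at 1000 nM (6 of 36 called; adjusted p = 1.56e-25, and adjusted p = 0.0499 with an estimated correlation). Oxidative phosphorylation genes gained (0 of 32; adjusted p = 3.61e-10 and 0.00928) and p53 targets gained (1 of 29; adjusted p = 3.27e-07 and 0.215). Ribosome biogenesis genes lost with 0 of 21 called, a shift that held (adjusted p = 6.11e-05 and 0.0456). NF-kB targets (1 of 22; adjusted p = 0.00106 and 0.523) and ribosomal proteins (0 of 35; adjusted p = 0.0218 and 0.523) gained. From 6 h to 24 h at 1000 nM, histone genes gained (13 of 28; adjusted p = 2.08e-08, and adjusted p = 0.236 with an estimated correlation). So did immediate early genes (13 of 30; adjusted p = 3.63e-07 and 0.236), interferon-stimulated genes (12 of 29; adjusted p = 0.000212 and 0.37), p53 targets (13 gained and 1 lost of 29; adjusted p = 0.000544 and 0.37) and TGF-beta and BMP targets (5 of 15; adjusted p = 0.00473 and 0.236). Cholesterol synthesis genes lost (4 of 14; adjusted p = 0.000678 and 0.236), as did replication genes (9 lost and 1 gained of 34; adjusted p = 0.00553 and 0.661) and DNA repair genes (3 of 27; adjusted p = 0.0226 and 0.591). Ribosomal proteins (0 of 35; adjusted p = 0.0369 and 0.661) and ribosome biogenesis genes (1 of 21; adjusted p = 0.0392 and 0.661) were shifted down too. For 100 nM from 2 h to 6 h, p53 targets gained with 0 of 29 called, a shift that held (adjusted p = 0.0119 with an estimated correlation), and ribosome biogenesis genes lost with 0 of 21 called, which held as well (adjusted p = 0.0119 likewise). Mitotic genes (adjusted p = 8.37e-19 and 0.0638) and the unfolded protein and integrated stress response (0.044 and 0.112) were shifted down and oxidative phosphorylation genes up (0.00106 and 0.0638), with no member called. From 6 h to 24 h at 100 nM, 2 p53 targets gained (adjusted p = 4.29e-10, and adjusted p = 0.0512 with an estimated correlation) and 4 mitotic genes lost (adjusted p = 4.99e-14 and 0.226). In that comparison 8 more lists passed, none with an estimated correlation (lowest adjusted p = 0.0512). NF-kB targets, interferon-stimulated genes, immediate early genes and apoptosis regulators were shifted up, and cholesterol synthesis genes, ribosome biogenesis genes, heat shock proteins and replication genes down. All 9 genes that fell with 1000 nM at 2 h also fell at 6 h, as all 7 that rose also rose. Of the calls at 6 h, 67 of the 72 that rose at 6 h rose at 24 h (6.5 for independent lists), 119 of the 163 that fell also falling (16.83).

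Limma's F-test found genes whose change with 1000 nM differed between tissues of origin. Some genes were near background in the other tissues, with a mean untreated level of about 3 to 4 (SOX10, IKZF1, RNF43, RXRG, CPN1 and MYEF2 below). No fall could be seen there, so for these genes a difference in response cannot be told apart from the difference in untreated level. Of the 104 genes at 6 h and 535 at 24 h, 28 and 198 had a mean untreated level above that of the median gene (5.76) in each tissue. Of all 11963 genes, 4878 and 4803 had, a larger share, clearly so at 6 h and slightly at 24 h. Low levels in some tissue may thus add to the counts, which was not tested. At 6 h, SOX10, the neural crest transcription factor, stood at −1.34 ± 0.88 in 9 melanoma lines (limma F-test over tissues, adjusted p = 8.52e-07), from an untreated level of 9.17 against 3.79. IKZF1, a lymphoid transcription factor, stood at −1.03 ± 0.55 in 6 leukemia lines (adjusted p = 8.52e-07; untreated level 8.31 against 4.13). CCN1, a matricellular growth factor target, stood at −2.71 ± 1.07 in 6 CNS lines and −1.11 ± 1.26 in 9 lung lines. It stood at 0.85 ± 0.55 in 6 colon lines and 0.46 ± 0.21 in 6 leukemia lines (limma F-test, adjusted p = 3.11e-05). Its untreated level was 11.48 in CNS lines against 8.60 elsewhere, 6.05 in colon lines and 4.02 in leukemia lines. The leukemia level is near background, where no fall could be seen. In 6 colon lines, RNF43, an inhibitor of Wnt receptors, stood at −1.30 ± 0.47 (adjusted p = 4.43e-05; untreated level 7.08 against 4.19), and CCDC186 at 0.97 ± 0.36 against 0.04 (adjusted p = 9.86e-06; 4.46 against 4.51). MYBL1 stood at 1.04 ± 0.49 in leukemia lines against 0.21 in all other lines pooled (limma F-test, adjusted p = 0.000116). Its untreated level was 5.51 in leukemia lines against 8.65 in the others.

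At 24 h the genes with the smallest p were led by melanoma. RXRG, a retinoid X receptor, stood at −3.03 ± 1.54 in 7 melanoma lines (limma F-test, adjusted p = 2.77e-08), from an untreated level of 6.85 against 3.30 elsewhere, where it could not fall further. CPN1 stood at −2.25 ± 1.09 (adjusted p = 3.15e-08; 6.60 against 3.57) and MYEF2 at −2.21 ± 1.32 (adjusted p = 2.1e-06; 6.15 against 3.37), with the same limit. IL24, a cytokine of the IL-10 family, stood at 4.78 ± 2.18 in these melanoma lines, 2.33 ± 0.99 in 2 prostate lines, 0.79 ± 1.31 in 4 breast lines and 0.62 ± 1.13 in 8 lung lines (adjusted p = 9.68e-07). Its untreated level was 4.15 in melanoma lines and 3.95 elsewhere, where background limits the change that can be seen, so these sizes are not exact. In 6 colon lines TRIM10 stood at 1.38 ± 0.30 (adjusted p = 9.68e-07) and ADAP1 at −1.86 ± 0.81 (adjusted p = 8.4e-06; untreated level 7.97 against 5.47). ANXA2, annexin A2, stood at 1.11 ± 0.51 in 3 leukemia lines and 0.72 ± 0.33 in 7 melanoma lines (adjusted p = 2.08e-06), from untreated levels of 9.87 in leukemia lines against 13.09 elsewhere, near the top of the scale, and 12.41 in melanoma lines. With 1000 nM at 2 h, PLK2, a p53-inducible kinase, stood at 0.85 ± 0.31 in 9 melanoma lines and −0.52 in 6 CNS lines (limma F-test, adjusted p = 0.00661). Its untreated level was 8.51 in melanoma, 10.17 in CNS and 4.05 in leukemia lines, the last near background. With 100 nM at 24 h, ARHGAP25 stood at 1.08 ± 0.29 in 4 leukemia lines against 0.01 (limma F-test, adjusted p = 0.000849) and the syndecan SDC1 at 1.16 ± 0.71 in melanoma lines (adjusted p = 0.006). The untreated level of ARHGAP25 was 5.09 in leukemia lines and 4.31 elsewhere, where background limits the change that can be seen. That of SDC1 was 6.02 in melanoma lines against 8.42.

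In all, the limma F-test found 3 genes at 2 h, 104 at 6 h and 535 at 24 h with 1000 nM, and 68 at 24 h with 100 nM. With 100 nM it found 0 genes at 2 h and 0 at 6 h (604 and 705 at an unadjusted p under 0.05). The counts at 6 h with 1000 nM and at 24 h with 100 nM were 54 and 31 without leukemia lines and 161 and 111 without the 2 prostate lines. With tissues shuffled over the lines, 6 of 100 shuffles counted at least as many genes as the real tissues for 100 nM at 24 h. For 1000 nM it was 3 of 100 at 6 h and 4 of 100 at 2 h. Of 36 tests of gene lists between tissues, none passed, the lowest adjusted permutation p being 0.0883, shared by the histone genes with 1000 nM at 24 h (F = 3.63, permutation p = 0.00314). The histone list had a mean of 1.564 ± 0.396 in melanoma lines and 0.38 ± 0.449 in ovarian lines.

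**Figure D3:**
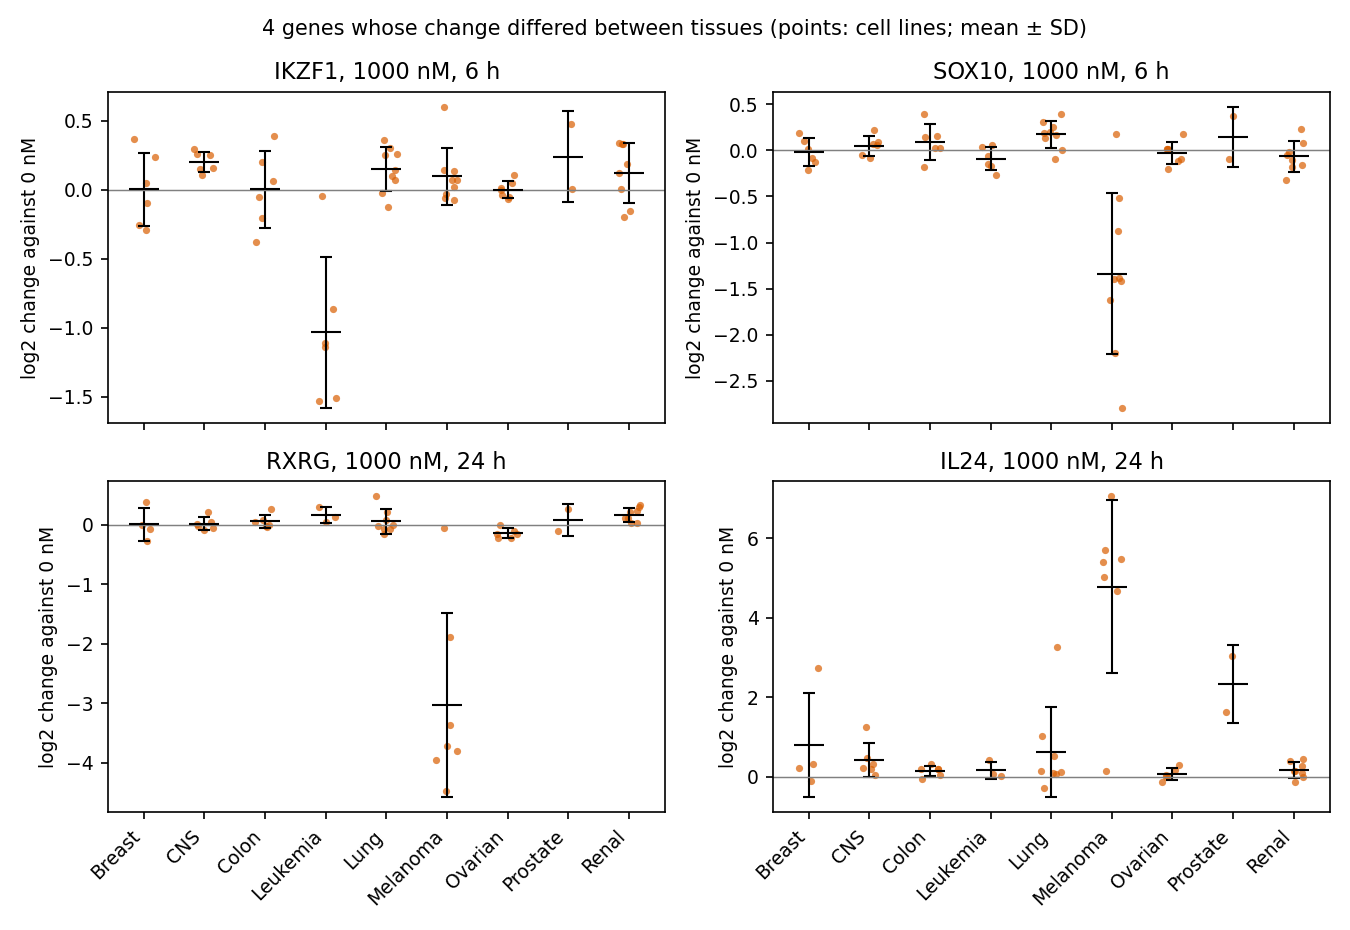
Log2 change with 1000 nM in each cell line, by tissue of origin, of genes with small p between tissues. The 9 melanoma lines averaged −1.34 for SOX10 at 6 h, and 7 melanoma lines averaged 4.78 for IL24 at 24 h, from an untreated level near background.

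Untreated expression was set against the response in 36 relations across lines. Lines with more MDM2 transcript before treatment had larger rises of the p53 targets (the mean over 0 nM arrays against the list mean). The MDM2 level came from a probe set ending in _s_at or _x_at, without which the MDM2 call with 1000 nM at 24 h ended. No value of the relation with another probe set is given here. With 1000 nM at 6 h, Pearson's r was 0.614 (n = 59; two-sided permutation p = 1e-05, the smallest that the permutations can give; adjusted p = 0.00036), and Spearman's rho 0.538 (permutation p = 2e-05). There r was 0.612 without the 2 lines farthest from the median and 0.581 with tissue means removed. With 1000 nM at 24 h, r was 0.568 (n = 50; permutation p = 4e-05; adjusted p = 0.00072), and rho 0.438 (permutation p = 0.00153). Here r was 0.524 without 2 lines and 0.471 within tissues. With 100 nM at 24 h, r was 0.52 (n = 57; permutation p = 9e-05; adjusted p = 0.00108), and rho 0.548 (permutation p = 2e-05), with r at 0.571 without 2 lines and 0.493 within tissues.

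ABCB1 before treatment was related to the size of the response, taken as the SD of the change over all genes, with 1000 nM at 24 h (r = −0.538, n = 50; two-sided permutation p = 0.00041; adjusted p = 0.00369). Spearman's rho was −0.143 (permutation p = 0.319), and r was −0.09 without NCI-ADR-RES and HCT-15, so the relation rests on these 2 lines. Within tissues r was −0.573. Untreated TOP2A and TOP2B, the transcripts of the drug's targets, gave no relation that passed with either response (r between −0.26 and 0.184), nor did ABCG2 or ABCC1.

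**Figure D4:**
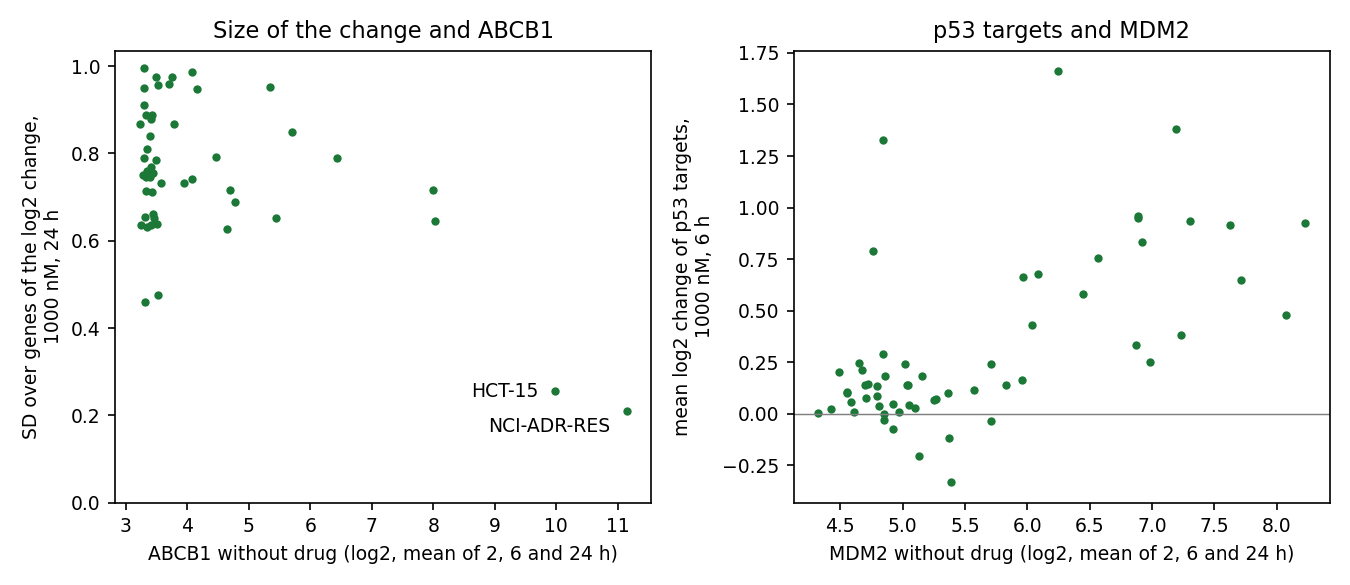
Left, the SD over genes of the log2 change with 1000 nM at 24 h against the untreated log2 level of ABCB1; right, the mean log2 change of the p53 targets with 1000 nM at 6 h against the untreated log2 level of MDM2. Each point is 1 line; NCI-ADR-RES and HCT-15 lay at 0.211 and 0.256 on the left, under the other lines, and r was 0.614 on the right.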

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

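The tests on T-47D, on NCI-ADR-RES and HCT-15 and on the actin controls were chosen only after the results were seen, as was the mean change among the histone tests.

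Of 28 histone genes, 14 rose with 1000 nM at 24 h (list mean 0.848 ± 0.566; 47 of 50 lines above 0; list adjusted p = 1.66e-05, and adjusted p = 0.561 with an estimated correlation). Without _s_at and _x_at probe sets, which near-identical histone genes share, 7 of 21 genes rose (33.3%), a share that alone does not decide, and the list mean, a criterion added after that share was seen, was 0.557 ± 0.457 with 46 of 50 lines above 0, against shared probe sets as the whole cause. A lower mRNA yield raised by the normalization would lift the poly-A spike-ins as much, and the histone change exceeded theirs by 0.522 ± 0.695 (42 of 50 lines; permutation p = 1e-05, the smallest that the permutations can give). RNA quality would leave no rise at an unchanged actin difference, where the regression over lines gave 0.601 (SE 0.119, slope 1.164). The actin difference rose in 47 of 50 lines, so that point lies at the edge of the data. Noise in the actin difference would also raise the value there, so it does not exclude RNA quality. A change of histone transcripts with the drug may be followed up as a hypothesis, with mRNA yield and RNA quality left open. Whether such a change reflects polyadenylated histone transcripts or the cell cycle was not tested.

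NCI-ADR-RES and HCT-15 had the smallest changes with 1000 nM at 24 h (SD over genes 0.211 and 0.256; 0.459 to 0.996 in the other 48 lines). Arrays of another line are argued against by 0 of their 18 arrays lying closer to another line, and an exchange of dose labels by the largest difference between any of their arrays, 0.329, against a lowest value of 0.459 in the other lines. High ABCB1, the efflux pump that carries doxorubicin, and other differences of the 2 lines cannot be told apart: these lines had the highest untreated ABCB1 (11.14 and 9.98), and in the other 48 lines r with the SD was −0.09 (permutation p = 0.543). CAKI-1 and UO-31, with ABCB1 levels of 8.02 and 7.99, had SDs of 0.646 and 0.716. Exact tests of the lines with the highest ABCB1 against the rest were run after the values were seen and support nothing, as they single out the lines that show the pattern.

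T-47D changed opposite to the other lines with 1000 nM at 24 h (r across genes with their mean change −0.706, next lowest line 0.123) and at 6 h (−0.584, next lowest −0.065). Relative to its untreated 2 h array, the array labelled 0 nM at 24 h carried 1.197 times the change of the other lines with 1000 nM (1.13 times at 6 h), where untreated arrays of the other lines lay between −0.099 and 0.084 (−0.146 and 0.271 at 6 h), and the array labelled 1000 nM carried 0.014 times (−0.031 at 6 h). The second value argues against an opposite response of the line, and 0 of its 9 arrays lay closer to another line. Both values are consistent with 0 nM and 1000 nM exchanged within the line at 6 h and 24 h, and whether at the bench or in the labels stays open. The labels were kept as given, and without T-47D 262 genes instead of 235 were called at 6 h and 2480 instead of 2315 at 24 h.

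The change with the drug differed between times, by a test of the difference itself, for 19 genes at 100 nM from 6 h to 24 h, 46 genes at 1000 nM from 2 h to 6 h and 1594 genes at 1000 nM from 6 h to 24 h. It differed between tissues for 535 genes at 24 h with 1000 nM. It also did for 3 genes at 2 h and 104 at 6 h with 1000 nM, and for 68 at 24 h with 100 nM. Chance is not excluded for the counts of 3, 104 and 68.

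Control probe sets outside the comparisons also moved with the drug. The hybridization controls stood at 0.066 ± 0.193 with 100 nM at 2 h, 0.137 ± 0.287 with 1000 nM at 2 h and 0.18 ± 0.334 with 1000 nM at 24 h. The poly-A spike-ins stood at −0.112 ± 0.313 with 100 nM at 6 h and 0.326 ± 0.814 with 1000 nM at 24 h. The actin 3' minus 5' difference rose by 0.212 ± 0.177 with 1000 nM at 24 h (47 of 50 lines), while that of GAPDH stood at 0.01 ± 0.09. The slope of GAPDH on the actin difference over all arrays, 0.55, would give 0.117. That slope includes 3 arrays with actin differences over 4, where the highest of the others was 1.86. It may not hold for a small shift, so these values do not decide on RNA degradation.

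The signs of the lines' changes were drawn at random for each of the 16 comparisons of doses and times. In each, 1 of 100 draws, the real one included, gave a count as large as the real one. That is the smallest share these draws can give, and it argues against random signs as the source of the counts. The real counts of called genes, with the highest of the other draws, were 16 and 0 with 1000 nM at 2 h, 235 and 0 at 6 h, 2315 and 0 at 24 h and 55 and 0 with 100 nM at 24 h. Between the doses they were 6, 111 and 1872 at 2, 6 and 24 h, and over time without drug 5, 3 and 20, each with 0 in the other draws. For the responses over time they were 46 and 0 for 1000 nM from 2 h to 6 h, 1594 and 64 from 6 h to 24 h, and 19 and 0 for 100 nM from 6 h to 24 h. Below the adjusted threshold without the fold minimum, they were 494 and 0 with 100 nM at 2 h, 1474 and 3 at 6 h, and 163 and 1 for the 100 nM response from 2 h to 6 h.

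Shuffling tissues over lines gave a count as large in 1 of 100 shuffles with 1000 nM at 24 h, the real one included (535 genes, highest other 32). This argues against chance as the source of that count. With 1000 nM it was 3 of 100 at 6 h (104, highest other 170) and 4 of 100 at 2 h (3, highest other 69). Chance is not excluded for these 2 counts, as single shuffles exceeded them and the shares were not corrected for the number of tissue tests. Nor is it excluded for 100 nM at 24 h, with 6 of 100 (68, highest other 377). At an unadjusted p under 0.05, 100 nM gave 37 of 100 at 2 h (604, highest other 1733) and 16 of 100 at 6 h (705, highest other 1135). Single shuffles counted several times the real number, 377 against 68 and 69 against 3, which a structure of the lines other than tissue or correlation between genes would give, and neither was tested.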

How the results depend on the processing

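Leaving out T-47D, SK-MEL-2 or the arrays with an actin difference over 1 was chosen only after the data were seen. Of 343 tests of named genes, 337 gave the same call in the joint fit, 341 with equal array medians, 334 after quantile normalization and 308 with the mean of all probe sets. The number was 329 in lines with all 9 arrays, 336 without leukemia lines, 339 without the 3 lines that share an origin, 337 without the actin arrays, 342 without SK-MEL-2, 338 without T-47D, 286 without cell line as a block, and 343 with trend and robust variances or the Wilcoxon test. Of the tests that could be run, 302 of 302 kept it among genes above the median level and 187 of 204 without _s_at and _x_at probe sets; a gene not called under either setting counts as the same. Of 132 list results, 99 kept their call with an estimated correlation, 117 without _s_at and _x_at probe sets, and between 120 and 130 under the other settings. The cause of a lost call was not tested, except that settings with fewer genes or lines have fewer to count. A dim probe set limits the change that can be seen, which would not turn its direction. With 1000 nM at 24 h, the LSS probe set with a level of 3.66 rose by 0.33 ± 0.47 (n = 50). The one used stood at −0.77, and the opposite directions are left unexplained.

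Without cell line as a block, the pairing of samples by line was lost, and 7 genes were called with 1000 nM at 2 h, 1 between the doses at 2 h, 33 with 100 nM at 24 h, 1, 0 and 5 untreated (6 h against 2 h, 24 h against 6 h, 24 h against 2 h), 0 for the 100 nM response from 6 h to 24 h and 18 for the 1000 nM response from 2 h to 6 h; the other counts were within 1.5 times. Without _s_at and _x_at probe sets 8369 genes were tested, and fewer were called with 1000 nM (7 at 2 h, 134 at 6 h, 1424 at 24 h), between the doses (3, 64 and 1162) and with 100 nM at 24 h (27). IFI44 between the doses at 24 h lost its call there, from −0.65 to 0.127 (p = 0.221). Among genes above the median level, 3 were called untreated from 2 h to 6 h, and in lines with all 9 arrays 3 between the doses at 2 h. Between tissues with 1000 nM at 2 h, 1 gene was left without leukemia lines, 1 above the median level and 1 without the actin arrays. With 1000 nM at 6 h the counts were 54 without leukemia lines, 161 without prostate lines and 46 above the median level; with 100 nM at 24 h they were 31 and 111 without leukemia and without prostate lines; with 1000 nM at 24 h 341 above the median level.

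Without T-47D, the histone list lost its call with 100 nM at 6 h and 24 h and the ribosomal proteins with 1000 nM at 6 h, the interferon list gained one with 100 nM at 6 h, and no count moved by over 1.5 times. Without SK-MEL-2, MYC between the doses at 2 h was called (−0.59), the replication list gained a call with 1000 nM at 6 h and the cholesterol list lost its call with 1000 nM at 24 h. The relation to gene length was not run.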

Other observations

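The values of LOX, of BT-549 and NCI-H322M and of ABCC1 and ABCB1 against the p53 list, and the choice of NFKB2, ICAM1 and TNFSF9, were singled out only after they were seen.

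In the melanoma line LOX, SOX10 and RXRG stood at 3.63 and 3.27 without drug, near background, where no fall could be seen. IL24 changed by 0.15 in LOX with 1000 nM at 24 h, from an untreated level of 5.00, and by 4.67 to 7.06 in the other 6 melanoma lines, from levels of 3.71 to 4.28, where background limits the change that can be seen. These are single arrays with no replicate check.

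NFKB2 rose with 1000 nM at 24 h in 48 of 50 lines and ICAM1 in 46 of 50. TNFSF9 had risen in 53 of 56 lines at 2 h.

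The relation of untreated MDM2 to the rise of p53 targets might have come from MDM2 being in the list. With the list of 28 genes without MDM2, r with 1000 nM at 6 h was 0.617 (permutation p = 1e-05, the smallest that the permutations can give), against 0.614 with it, and without T-47D it was 0.622 for the whole list. The state of TP53 in these lines, not analysed here, was not tested.

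With tissue means removed, untreated ABCC1 and the p53 list were related with 1000 nM at 6 h (r = 0.502) and 24 h (r = 0.543). Untreated ABCB1 and the p53 list were related at 24 h without NCI-ADR-RES and HCT-15, with tissue means kept (r = 0.573). For ABCB1 in all lines with tissue means removed, r was 0.122. In all lines with tissue means kept, none of the 3 passed (r = 0.306, 0.242 and 0.227, adjusted permutation p = 0.127, 0.272 and 0.291). With 1000 nM at 6 h, BT-549 and NCI-H322M had the next lowest correlations with the other lines' mean change (−0.065 and −0.006) after T-47D, the 3 lines below 0. Relative to the untreated 2 h array, their 6 h arrays labelled 0 nM carried 0.271 and 0.214 times that change. Those labelled 1000 nM carried 0.197 and 0.207 times at 6 h, and 0.89 and 0.518 times at 24 h. The 0.271 of BT-549 is also the upper end of the untreated range set beside T-47D at 6 h. The cause was not tested.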
